A study of Mus musculus with 6 samples.

How the data were processed

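Total RNA from hearts of mice on a mixed C57BL/6 x 129S6 background was hybridised to 6 Affymetrix arrays, 3 of Nkx2.5-Cre controls and 3 of hearts in which Nkx2.5-Cre switched on the microRNA cluster of miR-302 and miR-367 at Rosa26, called transgenic. Per the labels' protocols, 100 ng of total RNA was made into cDNA with a poly(T) primer, amplified by in vitro transcription and labelled with biotin. The deposited values are log2 expression values, 1 per probe and array, and the submitters' processing notes name oligo, RMA and limma without versions. The background correction, the array annotation and any probe filter are not given in the sources used here. The quantiles of the 6 arrays were close but not equal, with a largest gap of 0.172 on the log2 scale, so the exact order of normalization and summarisation is unknown. No detection calls, slide numbers or scan dates were used here, and the number of arrays limits the precision.

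The table held 41345 probes. Gene names came from the platform's annotation, which gave 1 gene symbol for 23521 probes, several for 1814 and none for 16010. Only probes with 1 symbol were named. For 1082 genes with more than 1 probe, the probe with the highest mean over all 6 arrays was used, which left 22180 genes. Gene identifiers of 21994 of them were found in the RefSeq table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other, and 0 symbols were updated. No 2 arrays held identical values.

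The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are transgenic minus control on the log2 scale, with no filter on dim probes. Before the data were examined, 32 gene lists were fixed, 6 primary and 26 secondary, along with the tests, the alternatives and the rule for named genes. Of the list members, 62 had no probe of their own and were not analysed here. Lists were tested two-sided with camera at a preset correlation of 0.01, adjusted over all lists. With a correlation estimated per list, 0 of the 13 called lists held, with only 6 arrays to estimate it from. The 6 arrays leave 4 residual degrees of freedom. For the sarcomere (0.00842), cardiac transcription factor (-0.0229) and glycolysis (-0.0221) lists the estimate was below the preset value. A larger correlation thus did not cost these calls. The fry test asks whether the genes of a list move on balance one way and does not compare them with other genes. Some lists share members, such as Birc5 and Ect2 in the cell cycle and YAP lists.

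The rule for named genes took the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, passing over symbols of fixed forms (Gm with digits, Rik endings, LOC, RP, Olfr, Vmn, Snor, BC and AK with digits). These forms do not cover every symbol without a known function, so AW112010 was kept while F830016B08Rik was passed over. It also took up to 4 members of each list by smallest p, and the cluster, Rosa26, Hippo, natriuretic peptide, myosin, cyclin and Mki67 genes in any case. Genes outside the rule are said to be chosen after their values were seen.

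The steps were tested on simulated data for the comparison of transgenic with control over 22180 genes. Of 50 genes changed at each size, 2% were recovered at 1.25-fold, 42% at 1.5-fold, 84% at 2-fold and 100% at 4-fold, and 3 unchanged genes were called. In that simulation 200 genes were changed, while the real data called 2465, of which 958 changed by at least 1.5-fold. With fewer changed genes the adjustment is stricter, so these shares may understate recovery in the real data. With no gene changed, 0 genes and 0 lists were called, and a list shifted by 0.5 on the log2 scale was called with 0 others. The simulated genes were drawn independently, so these data cannot show how the list test behaves when members of a list correlate. In the real data the estimated correlation of the cell cycle list was 0.242.

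Alternatives left out the dimmest genes (a share of 0.333 by mean over the 6 arrays), averaged the probes of a gene, tested every probe, normalized by quantiles again, centred each array on its median, used an intensity trend with robust variance estimation, array weights, the replicate number as a block or a minimum fold of 1.5, left out each array in turn, and used fry or an estimated correlation for lists. A sex term was added after seeing the data. A planned test of genes with seed sites for the cluster's microRNAs was not run, because 3' UTR sequences were not used here. Genes near Rosa26 were compared with the rest by Fisher's exact test.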

Results

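Gene expression was measured in mouse hearts on 6 Affymetrix arrays, 1 heart sample per array. In 3 control samples the mice carried only Nkx2.5-Cre, a Cre recombinase driven in cardiac progenitors and their descendants. In the other 3, here called transgenic hearts, Cre also switched on a copy of the microRNA cluster of miR-302 and miR-367 placed at the Rosa26 locus. The cluster is best known from embryonic stem cells, and the series asks how its overexpression affects proliferation and differentiation of heart muscle cells. The labels give 2 ages for these hearts. The source name and the harvest protocol say postnatal day 14, while the age field says E14. In control hearts Myh6, the adult alpha myosin heavy chain, had a mean log2 value of 12.67, and Myh7, the slow beta form, 7.18. Rpl3l, which replaces Rpl3 after birth, had 8.95, and Tnni1, which the fetal heart uses, 7.995. As far as probes of different genes compare, the Myh6, Myh7 and Rpl3l values argue for a postnatal age. The Tnni1 value does not, and the label conflict itself stays unresolved. The deposited log2 values had medians between 5.45 and 5.54 on the 6 arrays. Arrays of the same group correlated at 0.982 to 0.989 across all probes, and arrays of different groups at 0.974 to 0.983. The first principal component held 54.3% of the variance and had all controls on one side and all transgenic hearts on the other. The labels do not say whether the samples came from separate animals. Each group held hearts of both sexes by Xist and Y-linked genes, so at least 2 animals, and p-values measure the spread between these samples, which may be technical in part, and the number of arrays limits the precision.

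The first comparison checked the genotype. All 5 microRNA genes of the cluster were higher in every transgenic heart than in any control heart. The Mir302c probe rose from a log2 value of 3.37 ± 0.34 (SD, n = 3) to 9.98 ± 0.017 (SD, n = 3), a log2 fold change of 6.61 with an SE of 0.15 (limma adjusted p = 1.674e-07). Mir302a rose by 6.32, Mir367 by 4.51, Mir302d by 4.25 and Mir302b by 2.99 on the log2 scale, the last with the largest adjusted p of the cluster, 0.0002713. In control hearts these probes lay between the 0.0225 and 11.5 percentile of all genes tested, close to the bottom of the scale, so the fold changes may be understated. The labelling protocol primed cDNA with poly(T), and mature microRNAs were not measured here. In the RefSeq annotation the endogenous cluster lies inside Larp7, which encodes a 7SK RNA binding protein. Larp7 had a log2 fold change of -0.04 (95% interval -0.29 to 0.21, adjusted p = 0.8596). Nkx2-5, the source of the Cre driver, had a value of 0.08 (adjusted p = 0.6156).

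At the transgene locus, Setd5, which neighbours Rosa26, rose by 0.78 on the log2 scale (SE 0.094, adjusted p = 0.001649). Gt(ROSA)26Sor itself was higher by 0.39 (SE 0.088, adjusted p = 0.02408). That call was lost without control 1 (adjusted p = 0.0852), control 2 (0.0669), transgenic 1 (0.0841), transgenic 2 (0.0679) or transgenic 3 (0.0794). Thumpd3, on the other side of the locus, had a value of 0.13 (adjusted p = 0.4249).

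**Figure D1:**
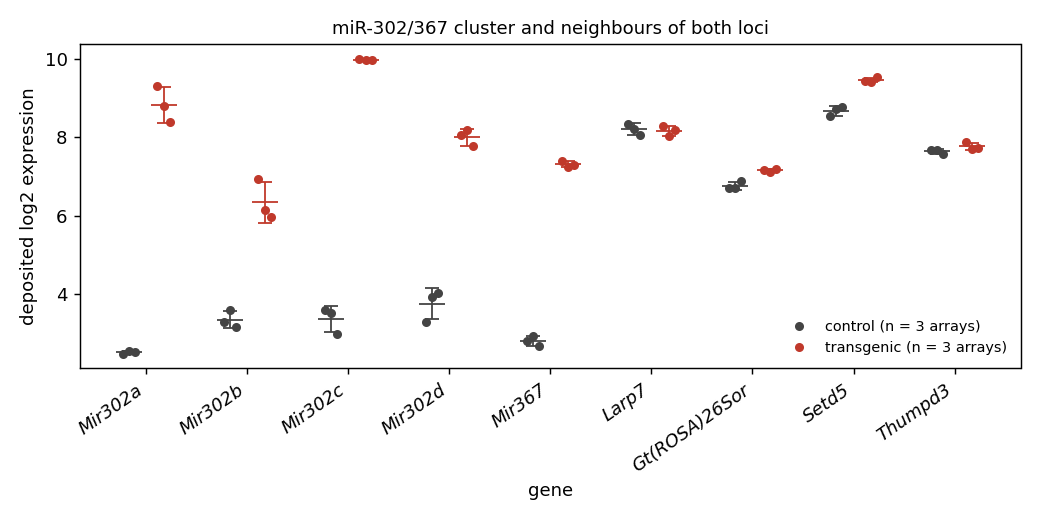
Deposited log2 expression (vertical axis) of the 5 microRNA genes of the cluster, of Larp7 and of genes at Rosa26 (horizontal axis), with 1 point per array for 3 control (grey) and 3 transgenic hearts (red), and bars for mean and SD. The cluster genes are far apart between the groups, with Mir302c at 3.37 in control and 9.98 in transgenic hearts, while the Larp7 points overlap.

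The main comparison asked which genes differ between transgenic and control hearts. Among genes taken by the naming rule, which passes over olfactory receptor genes, the largest rise outside the cluster was that of Tnni1, the slow skeletal troponin I that the fetal heart uses. Tnni1 went from 7.995 ± 0.12 to 10.86 ± 0.047 (SD, n = 3 each), a 7.30-fold difference (adjusted p = 1.482e-06). The largest fall by the same rule was that of Mylk4, a myosin light chain kinase family member, from 9.56 ± 0.25 to 5.75 ± 0.12 (SD, n = 3 each), a log2 fold change of -3.81 with an SE of 0.13 (adjusted p = 2.227e-06). In all, 2465 of 22180 genes (11.1%) passed an adjusted p of 0.05, of which 1187 were higher and 1278 lower in transgenic hearts. Of these, 113 rose and 111 fell by at least 2-fold. The values of the groups did not overlap for 6852 genes (30.9%), where chance gives 10%. The count of called genes was 1378 without control 1, 1217 without transgenic 1, 1171 without transgenic 2 and 1553 without transgenic 3.

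Among the other genes with the largest rises, Pcbd1, a cofactor of HNF1 that also recycles tetrahydrobiopterin, rose by 2.58 on the log2 scale. Ptgds, a prostaglandin D synthase, rose by 2.23, and Myoz1, a calcineurin-binding Z-disc protein of fast skeletal muscle, by 2.20. Ncam1, a neural cell adhesion molecule, rose by 2.03, and Hif3a, a hypoxia-inducible factor subunit, by 1.92. Adjusted p-values of these 5 genes ranged from 8.523e-05 for Pcbd1 to 0.002332 for Hif3a. Hamp, which encodes the iron hormone hepcidin, was higher by 2.04 with an SE of 0.49 (adjusted p = 0.03069). That call was lost without control 1 (adjusted p = 0.0931), control 2 (0.0785), transgenic 2 (0.103) or transgenic 3 (0.102), and with an intensity trend in the variance model (0.0675).

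Among the other genes with the largest falls, Acss1, a mitochondrial acetyl-CoA synthetase, fell by 2.38 on the log2 scale, Ckmt2, the sarcomeric mitochondrial creatine kinase, fell by 2.15, and Fitm2, which acts in lipid droplet formation, fell by 1.88. Rpl3l, the ribosomal protein of striated muscle that replaces Rpl3 after birth, fell by 2.02. Lrtm1 fell by 2.87, Itgb6, an integrin subunit, fell by 2.39, and Alpl, an alkaline phosphatase, fell by 2.07. Sh3rf2 fell by 2.00, AW112010 fell by 1.97, Arhgap20 fell by 1.88 and Klhdc8a fell by 1.86. Of these 11 genes the largest adjusted p was 0.0006512, for AW112010. Acss1 and Alpl each have a second, dimmer probe, whose log2 fold changes were -0.21 (adjusted p = 0.5329) and -0.41 (adjusted p = 0.1712) in the fit of every probe.

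Cell cycle genes were higher in transgenic hearts. Of 60 measured members of the list, 39 rose and 0 fell, and 51 rose and 0 fell when adjusted over the list alone. At an unadjusted p under 0.05 the list held 51 genes. The median log2 fold change was 0.53. Cks2, a cyclin-dependent kinase subunit, rose by 1.62 and Ect2, a cytokinesis factor, by 1.19. Birc5, the mitotic protein survivin, rose from 5.29 ± 0.036 to 6.30 ± 0.058 (SD, n = 3 each), and Mki67, the proliferation marker, from 6.91 ± 0.086 to 7.73 ± 0.033 (SD, n = 3 each). The D cyclins fixed in advance did not pass the test, with -0.20 for Ccnd1 (adjusted p = 0.47) and -0.08 for Ccnd2 (adjusted p = 0.6308). The list passed the camera test (adjusted p = 1.41e-27). The call was lost with an adjusted p = 0.203 with an estimated correlation.

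Of 18 measured cell cycle inhibitors, 5 fell and 2 rose, and 6 fell and 4 rose when adjusted over the list alone. Cdkn1a, the p53-responsive inhibitor p21, fell by 1.39 on the log2 scale (adjusted p = 0.00376). Tob2, an antiproliferative protein, fell by 1.16 and Ccng1, a p53 target, fell by 0.65. Cdkn3, a phosphatase whose own expression peaks in dividing cells, rose by 0.89. The list as a whole did not pass (median -0.11, camera adjusted p = 0.275).

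Genes of the fetal heart went both ways. Of 32 measured members, 10 rose and 5 fell, and 13 rose and 7 fell when adjusted over the list alone. Beside Tnni1, Myh7, the slow beta myosin heavy chain, rose by 1.84 with an SE of 0.20 (adjusted p = 0.0009336). Nppa, atrial natriuretic peptide, rose by 1.20 (adjusted p = 0.003401), Cnn1, a smooth muscle calponin, rose by 1.41, and Slc2a1, the glucose transporter of the fetal heart, rose by 0.93. A second, dimmer Slc2a1 probe had a value of -0.02. Acta1, skeletal alpha-actin, fell by 0.79 (adjusted p = 0.002545). Nppb had a value of 0.27 (adjusted p = 0.5321). The list passed at an adjusted p = 0.028 with a median of 0.08, and not with an estimated correlation (adjusted p = 0.221). It also missed the threshold without control 2 (0.0565) or transgenic 2 (0.0505), with the dimmest genes left out (0.0713) and with renewed quantile normalization (0.0508).

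The sarcomere and adult cardiomyocyte list held 33 measured genes, of which 6 fell and 0 rose, and 10 fell and 2 rose when adjusted over the list alone. Besides Ckmt2, Tcap, the Z-disc protein telethonin, fell by 0.89, Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 0.83, and Myoz2, a calcineurin-binding Z-disc protein, fell by 0.59. Myh6, the adult alpha myosin heavy chain, was at 12.67 ± 0.041 in control and 12.58 ± 0.014 in transgenic hearts (SD, n = 3 each, adjusted p = 0.5515). The list passed with a small median of -0.09 (camera adjusted p = 0.0276), and not with an estimated correlation (adjusted p = 0.221). The call was also lost without control 3 (0.0816), with array weights (0.0525) and with renewed quantile normalization (0.144).

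**Figure D2:**
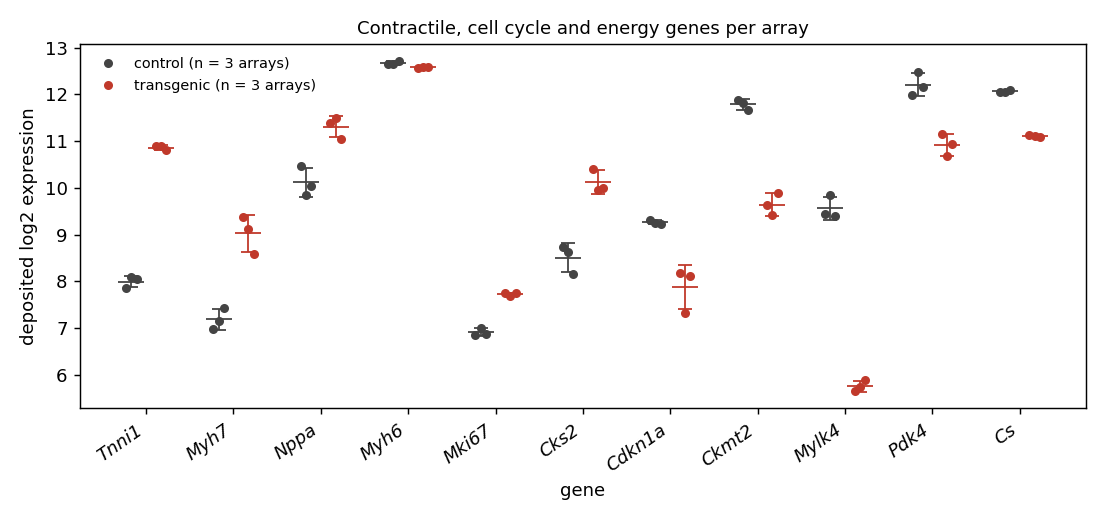
Deposited log2 expression (vertical axis) of contractile, cell cycle and energy genes (horizontal axis), with 1 point per array for 3 control (grey) and 3 transgenic hearts (red), and bars for mean and SD. Tnni1, Myh7, Nppa, Mki67 and Cks2 lie higher and Cdkn1a, Ckmt2, Mylk4, Pdk4 and Cs lower in transgenic hearts, while Myh6 had a log2 fold change of -0.09, with an adjusted p of 0.5515.

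Genes of fatty acid oxidation fell. Of 29 measured members, 16 fell and 0 rose, and 23 fell and 1 rose when adjusted over the list alone, with a median log2 fold change of -0.35 (camera adjusted p = 1.12e-10, and adjusted p = 0.231 with an estimated correlation). Pdk4, the kinase that shuts off pyruvate dehydrogenase, fell by 1.29 with an SE of 0.15. Plin5, a lipid droplet protein, fell by 0.91, Cpt2, which completes fatty acid import into mitochondria, fell by 0.77, and Acadvl, which starts the oxidation of very long chains, fell by 0.66. Of 36 oxidative phosphorylation and citrate cycle genes, 8 fell and 1 rose, and 12 fell and 1 rose when adjusted over the list alone (median -0.13, camera adjusted p = 0.000695, and adjusted p = 0.31 with an estimated correlation). Cs, citrate synthase, fell from 12.07 ± 0.017 to 11.11 ± 0.021 (SD, n = 3 each), and Uqcrc1 of complex III fell by 0.56. Of 22 glycolysis genes, 4 fell and 1 rose, and 8 fell and 4 rose when adjusted over the list alone (median -0.16). Slc2a4, the insulin-responsive glucose transporter, fell by 1.02 and Pfkm, muscle phosphofructokinase, fell by 0.67. That list passed at the threshold (camera adjusted p = 0.05), and an estimated correlation gave an adjusted p = 0.221. It also missed it without control 1 (0.0972), control 2 (0.0922), transgenic 1 (0.0507), transgenic 2 (0.112) or transgenic 3 (0.0584), with the dimmest genes left out (0.0599), with renewed quantile normalization (0.0685) and with centred arrays (0.0655).

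Endothelial markers were lower in transgenic hearts. All 22 measured markers had negative values, 11 fell and 0 rose, and 15 fell and 0 rose when adjusted over the list alone (median -0.39, camera adjusted p = 2.86e-08, and adjusted p = 0.221 with an estimated correlation). Ly6c1 fell by 1.23, and Pecam1, the endothelial adhesion molecule CD31, fell by 0.50. Macrophage and myeloid markers fell as well, 10 of 21 measured with 0 higher, and 14 with 0 higher when adjusted over the list alone (median -0.46, camera adjusted p = 2.86e-08, and adjusted p = 0.203 with an estimated correlation). C1qb, a complement subunit made by macrophages, fell by 0.96 and Csf1r, the receptor for macrophage colony-stimulating factor, fell by 0.94. Of 22 interferon response genes 8 fell and 0 rose, and 11 fell and 0 rose when adjusted over the list alone (median -0.38, camera adjusted p = 3.13e-05, and adjusted p = 0.203 with an estimated correlation). Igtp, an interferon-induced GTPase, fell by 0.62. Of 28 immediate early and stress genes 11 fell and 1 rose, and 14 fell and 1 rose when adjusted over the list alone (median -0.40, camera adjusted p = 4.34e-07, and adjusted p = 0.203 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, fell by 1.32 and Zfp36, an mRNA decay factor, fell by 1.01, while Gadd45b rose by 1.23.

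Cardiac transcription factors were among the few secondary lists called higher. Of 29 measured, 7 rose and 3 fell, and 10 rose and 4 fell when adjusted over the list alone (median 0.09, camera adjusted p = 0.0226, and adjusted p = 0.221 with an estimated correlation). Hey2, a Notch effector of the ventricular myocardium, rose by 1.77 with an SE of 0.17, and Tbx20, Tbx18 and Zfpm2 rose by 0.67, 0.66 and 0.62. Of 12 ventricular markers 3 rose and 1 fell, and 6 rose and 1 fell when adjusted over the list alone (median 0.17, camera adjusted p = 0.0226, and adjusted p = 0.221 with an estimated correlation). Irx4, a ventricular transcription factor, rose by 0.73 and Kcnip2, a subunit of the transient outward potassium channel, fell by 0.95. The ventricular call was lost without control 1 (adjusted p = 0.0503). Of 16 atrial markers 5 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone (median 0.21, camera adjusted p = 0.05, and adjusted p = 0.336 with an estimated correlation). Dkk3 rose by 1.49 and Myl4, the atrial light chain, by 1.09, while Kcna5, an atrial potassium channel, fell by 0.85. The atrial call was lost without control 2 (0.11), control 3 (0.0647), transgenic 2 (0.0945) or transgenic 3 (0.0948), with renewed quantile normalization (0.13) and with array weights (0.0619). All 3 calls were lost with the dimmest genes left out, at an adjusted p of 0.0641, 0.052 and 0.107.

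The Hippo pathway restrains organ growth, and some of its kinases are reported targets of the cluster. Of 30 measured members, 2 rose and 0 fell, and 1 rose and 0 fell when adjusted over the list alone. Tead2, a transcription factor at the end of the pathway, rose by 0.97 with an SE of 0.094 (adjusted p = 0.0005995). The kinases Lats2 and Stk4 had log2 fold changes of -0.25 and -0.27, each with an adjusted p = 0.0838. Mob1b had a value of -0.0047 (95% interval -0.18 to 0.17). Lats1 had 0.06, Sav1 0.12, Mob1a -0.18 and Yap1 0.03, with adjusted p-values from 0.3216 to 0.8986, and Stk3 was not analysed here. The list did not pass (camera adjusted p = 0.999), with a median of -0.04 and a mean of 0.0039 of the opposite sign.

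Of 33 YAP and TEAD targets, 5 rose and 4 fell, and 5 rose and 8 fell when adjusted over the list alone. The risers Birc5, Ect2 and Aspm are also known for roles in mitosis, and Birc5 and Ect2 are on the cell cycle list too. Igf1r, the receptor for insulin-like growth factor 1, rose by 0.83. The list did not pass (camera adjusted p = 0.999). Its median was -0.18, while its mean of 0.01 and the direction of the test were positive.

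Of 34 measured targets reported for the cluster, 5 fell and 1 rose, and 10 fell and 4 rose when adjusted over the list alone. Tob2 and Cdkn1a, given above, fell the most, and Bcl2l11, the proapoptotic protein Bim, rose by 1.31 with an SE of 0.12 (adjusted p = 0.0004351). The list did not pass, with a median of -0.14 (camera adjusted p = 0.22).

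**Figure D3:**
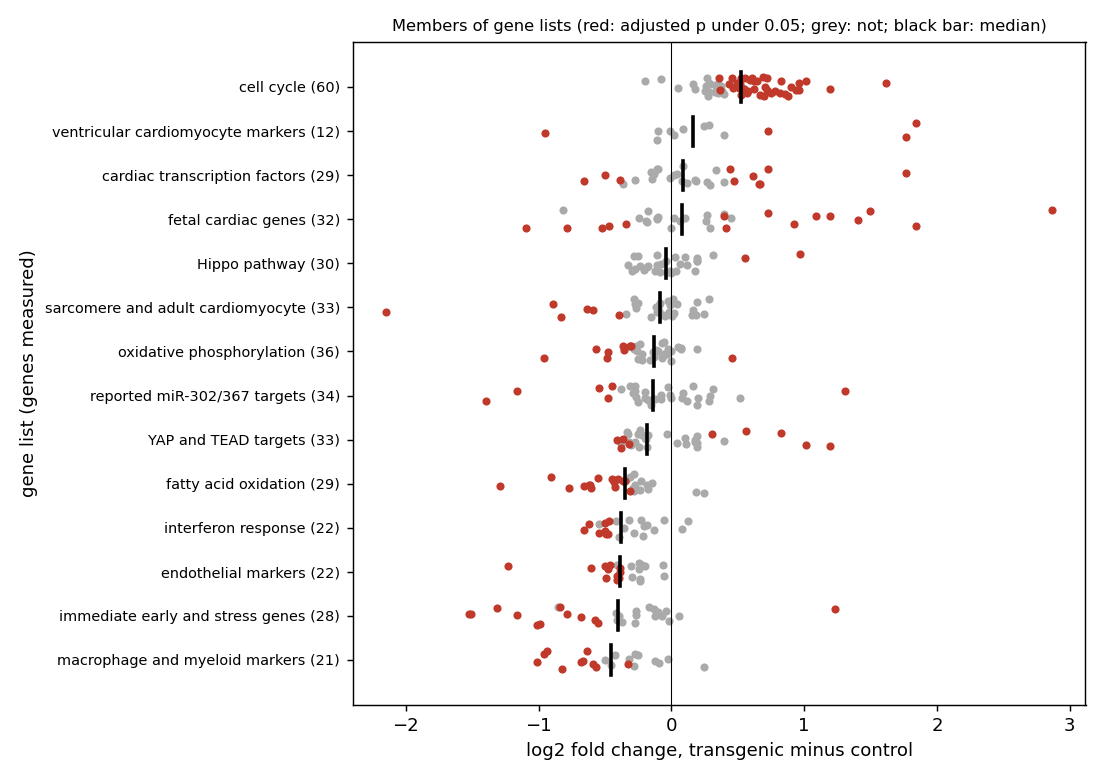
Log2 fold change, transgenic minus control (horizontal axis), of each measured member of 14 gene lists (vertical axis, with the number of genes measured), red where the adjusted p is under 0.05 and grey otherwise, with a black bar for the median. Shown are the 6 primary lists and the secondary lists whose rounded camera adjusted p is under 0.05. The glycolysis and atrial lists, called at a rounded 0.05, are not shown. The cell cycle list has a median of 0.53, the macrophage list of -0.46, and the fetal cardiac and cardiac transcription factor lists spread to both sides.

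The remaining lists did not pass. Calcium handling and ion channel genes had a median of -0.00091 (adjusted p = 0.682), with members on both sides. Trdn, the junctional protein triadin, fell by 1.29 and Kcnd2, a transient outward potassium channel, fell by 1.65, while Slc8a1, the sodium-calcium exchanger, rose by 0.97. In all 8 of its 31 genes fell and 4 rose, and 9 fell and 7 rose when adjusted over the list alone. Of 36 extracellular matrix genes 4 rose and 2 fell, and 5 rose and 7 fell when adjusted over the list alone (median 0.03, adjusted p = 0.275), with Timp1, a protease inhibitor, higher by 1.22 (adjusted p = 0.0003607). Of 16 fibroblast markers 5 fell and 0 rose, and 5 fell and 2 rose when adjusted over the list alone (median -0.16, adjusted p = 0.0738), with Pi16 lower at -1.24. That list passed without control 3, without transgenic 3 and with a sex term, down to an adjusted p = 0.0126. Smooth muscle and pericyte markers had a median of -0.21 (1 of 16 rose and 4 fell, 2 rose and 6 fell when adjusted over the list alone, adjusted p = 0.147). Epicardial and mesothelial markers had a median of -0.23 (2 of 14 rose and 2 fell, 3 rose and 4 fell when adjusted over the list alone, adjusted p = 0.682). Apoptosis genes had a median of -0.09 (5 of 23 rose and 4 fell, 5 rose and 5 fell when adjusted over the list alone, adjusted p = 0.546), with Fas, a death receptor, lower at -0.98. Pluripotency and dedifferentiation genes had a median of -0.05 (5 of 21 fell and 0 rose, with the same counts when adjusted over the list alone, adjusted p = 0.275), with Klf4 lower at -0.99.

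Markers of tissues that dissection could carry over were also measured. Adjusted over the list alone, the counts of calls in the lists of this paragraph were the same as those over all genes. Skeletal muscle markers had a median of -0.11 (1 of 21 rose, 2 fell, adjusted p = 0.188), with Tnni2 higher by 0.83 and Mybpc2 lower at -0.70. Neuron and Schwann cell markers had a median of -0.06 (3 of 12 fell, 0 rose, adjusted p = 0.188), with Sox10 lower at -0.55. Circadian clock genes had a median of -0.05 (1 of 17 fell, 0 rose, adjusted p = 0.211). By limma 0 genes were called in the adipocyte list (14 genes, 4 at an unadjusted p under 0.05, median -0.11, adjusted p = 0.132), in the lung epithelium list (14 genes, 2 at an unadjusted p under 0.05, median -0.10, adjusted p = 0.275) and in the lymphocyte and thymus list (16 genes, 3 at an unadjusted p under 0.05, median -0.06, adjusted p = 0.275). The same held for the erythroid list (9 genes, 1 at an unadjusted p under 0.05, adjusted p = 0.999), whose median of -0.02 and mean of -0.02 were negative and whose test was positive. The list of Rosa26 and sex-linked genes (7 measured, 2 rose, 0 fell) had a positive median of 0.13 and a negative mean of -0.08 (adjusted p = 0.147, and 0.0255 with a sex term).

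Sex was not given in the labels, and the hearts differed in it. The log2 value of Xist, the RNA of the inactive X chromosome, was 11.36 in control 2, 11.74 in transgenic 1 and 11.68 in transgenic 3, and between 4.59 and 5.01 in the others. The Y-linked genes Uty, Kdm5d and Eif2s3y, chosen after their values were seen, were high in those others. The groups thus held 1 and 2 Xist-high hearts. With a sex term, chosen after seeing the data, 1878 genes were called, 839 higher and 1039 lower, and the cell cycle median was 0.48 (adjusted p = 3.12e-25).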

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

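Probes without a gene symbol and probes with several were left out of the gene comparisons, and more of them were called higher than lower in transgenic hearts. Of 16010 probes without a gene symbol, 430 were called higher and 73 lower by limma over all probes. The largest rise was 2.41 on the log2 scale (SE 0.18, adjusted p = 0.003975) and the largest fall -2.22 (SE 0.25, adjusted p = 0.00931). Of 1814 probes with several gene symbols, 86 were called higher and 30 lower. The 86 include repeats of 1 signal, since several probes shared by Gm26504, Snord116l1 and Snord116l2 had the same values and a rise of 1.36. Among probes with 1 symbol, which the gene comparisons drew on, the counts were 620 higher and 647 lower. The share called in either direction was 3.14% without a symbol, 6.39% with several and 5.39% with 1. The difference between these classes of probes was not tested, and no explanation was tested for it.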

How the results depend on the processing

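The sex term was added after seeing the data, and all other alternatives were chosen before. With a minimum fold of 1.5, 958 genes were called, 480 higher and 478 lower, fewer by construction. In the fit of every probe 1136 were higher and 750 lower, against 1187 and 1278 among genes. These totals include probes without a symbol or with several. Probes with 1 symbol gave 620 higher and 647 lower in that fit. That is 5.39% of them, against 11.1% of genes in the gene fit. Leaving out 1 array gave 1171 to 2249 called genes, 569 to 970 higher and 602 to 1279 lower, with fewer arrays in each fit. The counts were 1378 without control 1, 1217 without transgenic 1, 1171 without transgenic 2 and 1553 without transgenic 3. Under every scaling, filter, variance model and left-out array that tested them, all called genes kept their direction except 1 of 2465 when probes of a gene were averaged. This was largely fixed in advance. The groups did not overlap for 2464 of the called genes, so leaving out 1 array could not reverse these. The intensity trend with robust variance estimation left the fold changes unchanged by construction.

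The cell cycle call held in 14 of 14 alternatives with the preset correlation, with medians of 0.45 to 0.61 when 1 array was left out, and not with an estimated correlation (0.5255, adjusted p = 0.203). The fetal cardiac list kept its direction and missed the threshold with the dimmest genes left out (0.26, adjusted p = 0.0713), renewed quantile normalization (0.066, 0.0508) and an estimated correlation (0.0819, 0.221), and without control 2 (0.0565) or transgenic 2 (0.0505). Its medians without 1 array were 0.050 to 0.11, and its adjusted p over the preset-correlation alternatives ran from 0.0142 to 0.0713. The sarcomere list missed it with renewed quantile normalization (-0.021, 0.144), array weights (-0.077, 0.0525) and an estimated correlation (-0.08809, 0.221), and without control 3 (0.0816), with medians of -0.094 to -0.068 without 1 array and an adjusted p from 0.0189 to 0.144. The number of secondary lists called higher was 0 with the dimmest genes left out and 0 with an estimated correlation, and 2 to 3 without 1 array. The number called lower was 0 with an estimated correlation, 11 with fry, and 6 to 8 without 1 array. For the sarcomere list the estimated correlation of 0.00842 was below the preset 0.01, so a larger correlation did not cost that call. The cause of these changes was otherwise not tested.

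The shared replicate numbers did not pair the arrays: same-numbered arrays correlated at 0.02, -0.13 and 0.01 in their deviations from the group means, and 0 of 6 correlated best with their own number. The replicate block gave 1996 called genes, 997 higher and 999 lower, and with it the glycolysis (0.0972) and atrial (0.0549) lists missed the threshold. The seed-site test and its stricter form were not run. Cluster probes near the bottom of the scale in controls limit the size of their fold changes.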

Other observations

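Tests of sex, blood cells, stage, dilution and short RNA probes, and the splits of the arrays, were chosen after the results were seen. Those of host genes and Dgcr8 were chosen before, but the host genes were judged by the upper limit of an interval, not by the share itself as first written. The rules that decide the tests of blood cells, dilution and short RNA probes were made stricter after a first outcome was seen. Under the first rules the values counted against blood cells and dilution and in favour of short RNA probes, and under the stricter rules all 3 explanations are left open.

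Beyond the genes described above, some of the next called genes by size were chosen after their values were seen. Fbn2, a fibrillin of fetal elastic fibres, rose by 1.77 on the log2 scale (SE 0.15, adjusted p = 0.0003097), Bmp5, a bone morphogenetic protein, by 1.66, and Lpar3, a lysophosphatidic acid receptor, by 1.69. Bex3 rose by 1.70 and its relative Bex4 by 1.56. Bcl6, a transcriptional repressor, fell by 1.74 (SE 0.089, adjusted p = 2.733e-05), Rxrg, a retinoid receptor, fell by 1.68, Dgat2, which makes triglycerides, fell by 1.61, and Nr4a1, an orphan nuclear receptor, fell by 1.52. Outside that ranking and also chosen after its value was seen, Mpc1, which carries pyruvate into mitochondria, fell by 1.42 from a control value of 12.80 (adjusted p = 0.0001319).

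The genes of this paragraph other than those near Rosa26 were also chosen after their values were seen. The olfactory receptor gene Olfr608 rose by 2.88 (SE 0.25, adjusted p = 0.0004112), while Olfr607 and Olfr609 next to it had 0.07 and -0.06. Rabgap1l rose by 0.95, and Gpr52 and Mir1927, which lie inside it, rose by 1.68 and 1.37. The interferon-inducible GTPase gene Iigp1 fell by 1.74, and its neighbours F830016B08Rik and BC023105 fell by 1.90 and 0.58. Of the 100 measured genes nearest to Rosa26, 11 were called, against 11.1% elsewhere (odds ratio 0.986, 95% interval 0.474 to 1.85, Fisher's exact test, two-sided, p = 1).

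Of 60 cell cycle genes 39 were called higher, with a list median of 0.53 and an adjusted p = 0.203 with an estimated correlation. Unequal sex was argued against as the whole cause by a median of 0.48 with a sex term. Dividing blood or thymus cells stay open. The 25 erythroid and lymphoid markers had a median of -0.045 (95% bootstrap interval -0.16 to 0.02), but 16 of them are among the dimmest genes. The other 9 had an interval of -0.39 to 0.07 and a highest value of 0.1134. That is below the rise of 0.2627 that was assumed, not measured, for such cells. Probes shared by several globin genes are not among the 25. Their log2 fold changes ran from -0.23 to 0.38 (limma over every probe, adjusted p of 0.5918 or more). A difference in stage between the groups stays open, since the median of 4 fetal growth genes was 0.20 with a range from -0.0038 to 0.40. The labels give the same 2 ages for both groups, so they do not bear on it. The genotype is among the open explanations.

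Of 43 endothelial and macrophage markers 21 were called lower, with a median of -0.39, and the lists had an adjusted p = 0.221 and 0.203 with an estimated correlation. Unequal sex was argued against as the whole cause by a median of -0.3873 with a sex term. A larger share of cardiomyocyte RNA would lower all other cell types alike and raise cardiomyocyte genes. Against it, 33 sarcomere and adult cardiomyocyte genes had a median of -0.088 (quartiles -0.27 and 0.011), but whether these genes also differ per cardiomyocyte was not tested, so it stays open. Some of these genes lay near the top of the scale, where a rise may be understated. Actc1 had a mean of 13.45 in controls, with an array maximum of 14.04 in control 1. The median of 39 fibroblast, smooth muscle and epicardial markers not on the matrix list was -0.23, with quartiles of -0.40 and 0.11 that overlap those of the first set, -0.53 and -0.24. A two-sided permutation test of the medians gave p = 0.0107, and a first form with matrix genes, 75 markers with a median of -0.07, gave p = 1e-05, but both treat genes as independent, and estimated correlations within these lists reached 0.56.

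MicroRNA genes outside the cluster were called higher in 45 of 467 cases and lower in 2, or 9.64% higher against 5.20% of other genes (Fisher's exact test, two-sided, p = 0.000141), and without transgenic 2 the count higher was 26. Neither this comparison nor that of snoRNA genes below was among the tests fixed in advance. Both treat genes as independent, while some microRNA genes share a host, such as Mir181a-2 and Mir181b-2 in Nr6a1. Of genes chosen after their values were seen, Mir133a-1 rose by 1.82, and Mir208a rose by 1.02 while its host Myh6 had -0.09. Of 74 snoRNA genes 11 were called higher and 0 lower (14.86%, Fisher's exact test, two-sided, p = 0.00156), but 3 without control 1, 3 without transgenic 1, 7 without transgenic 2, 6 without transgenic 3 and 18 with the dimmest genes left out, while their median stayed between 0.21 and 0.35, so whether probes of short RNA genes read higher in general stays open. Hosts were protein-coding genes that contain the microRNA gene by position, without regard to strand, so some may not share its transcript. Of 25 measured hosts 24% were called higher, against 5.20% of genes that are neither microRNA nor snoRNA genes. That share is under the 25% that the first rule counted against hosts, but its 95% interval of 9.36% to 45.1% reaches above it. The interval stays below a majority but does not settle how far microRNA genes follow their hosts. For saturated cleavage of microRNA precursors, Dgcr8 was named in advance and is not analysed here, while Drosha, chosen after its value was seen, had -0.08 (adjusted p = 0.7004).

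The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2465 genes and the highest other 5, in 1 of 10 splits as large. That other split follows sex. The real split called 13 lists and the other 9 splits 1 to 7 each, and its cell cycle median of 0.5255 compared with 0.2792 in the split that follows sex, again 1 of 10 each. The camera test of that list at the preset correlation gave an unadjusted p = 4.39e-29 in the real split and p-values down to 7.7e-17 in splits that mix the groups, where each side still holds 2 hearts of one group and 1 of the other and so keeps part of any group difference.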
